A study of Mus musculus with 12 samples.

How the data were processed

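RNA from the epididymal fat of 12 male C57BL/6J mice, 6 given saline and 6 given epinephrine, was extracted and made into libraries with a SMARTER mRNA-Seq kit, per the labels' protocols. Both injections were given at the same hour of the morning, and groups and replicate numbers were taken from the sample titles. The submitters' processing notes name FastQC, cutadapt, HISAT2, featureCounts and DESeq2 and the build mm10, with no versions; the strand setting and the annotation version are not given in the sources used here. Whether counts from genes that overlap on opposite strands were kept apart is therefore not known. The authors deposited one table of whole-number counts of reads per gene, with no normalization, for 27179 genes. A second deposited table holds variance-stabilized (VST) values on a log2-like scale for 20185 of these genes, ranging from 7.11 to 19.2 with a shared floor. The count table also lists gene lengths in bases, which were not used here.

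The counts per library summed to between 24821601 and 34405433. Gene models with an Entrez identifier but no symbol numbered 1312 and held between 0.253% and 0.315% of counts in each library; they were kept in library sizes and tests. Entrez identifiers were matched to symbols, gene types and GRCm38.p6 positions in a RefSeq gene table. Of the 16175 tested genes, 97.6% had a gene type. No 2 of the 66 pairs of libraries held identical counts, and the highest Spearman rho between libraries was 0.993.

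Genes were filtered with edgeR's filterByExpr (minimum count 10, minimum total count 15), scaled with TMM factors, and tested with edgeR's quasi-likelihood F test (glmQLFit with robust dispersion, glmQLFTest) in R 4.3.3 with edgeR 4.0.16 and limma 3.58.1. Adjusted p-values are Benjamini-Hochberg values over all tested genes, with a threshold of 0.05. The standard error of a log2 fold change is its unshrunk size divided by the square root of the F statistic. CPM are TMM-normalized, and log2 CPM use a prior count of 1. The common biological coefficient of variation was 0.451. Permutation tests of library measures were exact and two-sided, and with 6 libraries per group the smallest p they can give is 0.00216. Mice are separate animals per the labels, so the p-values of single genes and of library measures measure the spread between animals. Fisher's exact tests and the gene-list test at a preset correlation rest on genes as well, so their p-values do not measure that spread alone.

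Gene lists, 31 in all, were tested with limma's camera at a preset correlation of 0.01, with camera at an estimated correlation, and with fry. The symbols in the lists were matched to those in the files through a table of older names. The design, the lists, the rule for named genes and most alternatives were fixed before the data were examined. The rule named Gdf15, Adrb1 and Adrb3 always, and a result that it also gives is not reported here. It also named the 12 largest rises and 12 largest falls among genes past the threshold with an average log2 CPM of at least 1 and non-overlapping groups, leaving out predicted gene models and identifiers with no symbol. From each list it named up to 4 members with the smallest p. Other genes are named because a count of 5 or fewer holds them or as examples, chosen after their values were seen. Lists share members, so their counts are not independent.

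The alternatives were RLE, upper quartile and library-size scaling; no filter and a mean CPM of at least 1; DESeq2 1.42.0; limma-voom with sample weights; limma on the VST values; the replicate number as a block; listed age as a covariate; 1 surrogate variable (sva 3.50.0); a threshold of 0.01; and leaving out each library in turn. Added after seeing the data were the epididymal score (mean log2 CPM of the epididymis and testis list) as a covariate, the fit without the 3 libraries with Gpx5 above 0.5% of counts, and fits of numbers 1 to 3 and 4 to 6 alone.

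Replicate numbers come from the titles. Same-numbered libraries deviated from their group means together in all 6 pairs, with correlations across genes from 0.262 to 0.799. All were above 0.1, the rule set for pairs. That rule cannot tell pairs from a difference between numbers 1 to 3 and 4 to 6 that both groups share. Vehicle 1 to 3 correlated positively with each of epinephrine 1 to 3 and negatively with epinephrine 4 to 6, and vehicle 4 to 6 the reverse. In both groups the epididymal score was lower at numbers 4 to 6. The main fit took no pairs, and the number as a block is an alternative. Genes are not independent replicates, and only 3 of the 12 libraries correlated best with the library of their own number. The listed ages rise by 1 week from each sample to the next, and so follow the group and the number.

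The test was run on counts simulated from the libraries' own means and sizes. Of 98 genes changed 2-fold that were tested, 51 were recovered (52.0%), and of 93 changed 4-fold, 87 (93.5%), among 15988 genes tested. It called 144 genes, of which 6 (4.17%) were false, and called the changed list and 0 of 30 unchanged lists. The simulation drew each gene independently, with no epididymal difference between libraries, and took the unchanged lists from random genes. Its list result therefore does not carry over to lists whose members vary together.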

Results

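Epididymal white adipose tissue (eWAT), the abdominal fat pad attached to the epididymis, was profiled by RNA sequencing in 12 male C57BL/6J mice kept on chow. The vehicle group of 6 mice received saline into the peritoneum, and the other 6 received epinephrine at 0.5 mg/kg, the adrenal hormone that acts on alpha- and beta-adrenergic receptors. Tissue was taken 1 h after the injection. Each library is named by its group and replicate number. Between 24821601 and 34405433 reads were assigned to genes per library, with a mean of 29559000 ± 3733470 for vehicle and 26752400 ± 2567130 for epinephrine (SD, n = 6 each; exact two-sided permutation test, p = 0.143, adjusted p = 0.357 over 5 library measures). Reads assigned to 13 mitochondrial genome genes made up 3.36% ± 0.447 of counts with vehicle and 3.22% ± 0.170 with epinephrine (SD, n = 6 each; exact two-sided permutation test, p = 0.524, adjusted p = 0.739). These genes were unevenly counted, with ND2 at 1770 to 3290 CPM and COX2 at 9.72 to 16.7 CPM, and the cause was not tested. The TMM factor had the smallest p of the 5 measures. It was 1.04 ± 0.0476 with vehicle and 0.964 ± 0.0386 with epinephrine (SD, n = 6 each, exact two-sided permutation test, p = 0.0216, adjusted p = 0.108).

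The comparison asked how eWAT gene expression changed 1 h after epinephrine, and the series title places Gdf15 at its centre. Gdf15, which encodes a stress-induced circulating cytokine of the TGF-beta family, rose 14.6-fold, from 1.21 ± 0.391 to 17.6 ± 7.77 TMM-normalized CPM (read counts scaled to library size; SD, n = 6 each). Its log2 fold change was 3.87 (SE 0.35, edgeR adjusted p = 0.000108), and all 6 epinephrine libraries lay above all 6 vehicle libraries. Gdf15 (Entrez gene 23886) is a protein-coding gene on chromosome 8, positions 70629393 to 70632470 of GRCm38. Of 16175 genes tested, 428 were higher and 579 were lower with epinephrine, and 199 of the higher and 83 of the lower genes changed at least 2-fold. The groups did not overlap in 308 of the higher and 377 of the lower genes. The balance of higher and lower genes depended on the scaling. Scaled by library size alone, the split was 360 higher and 1448 lower, with the median of all genes at a log2 fold change of -0.11. Upper quartile scaling gave 388 higher and 766 lower, while RLE scaling gave 461 higher and 447 lower. The count of lower genes was 276 without vehicle 4, 314 without epinephrine 4, 353 without vehicle 1, 362 without epinephrine 3, 364 without vehicle 3 and 373 without epinephrine 5, and that of lower genes past 2-fold was 54 without vehicle 4.

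**Figure D1:**
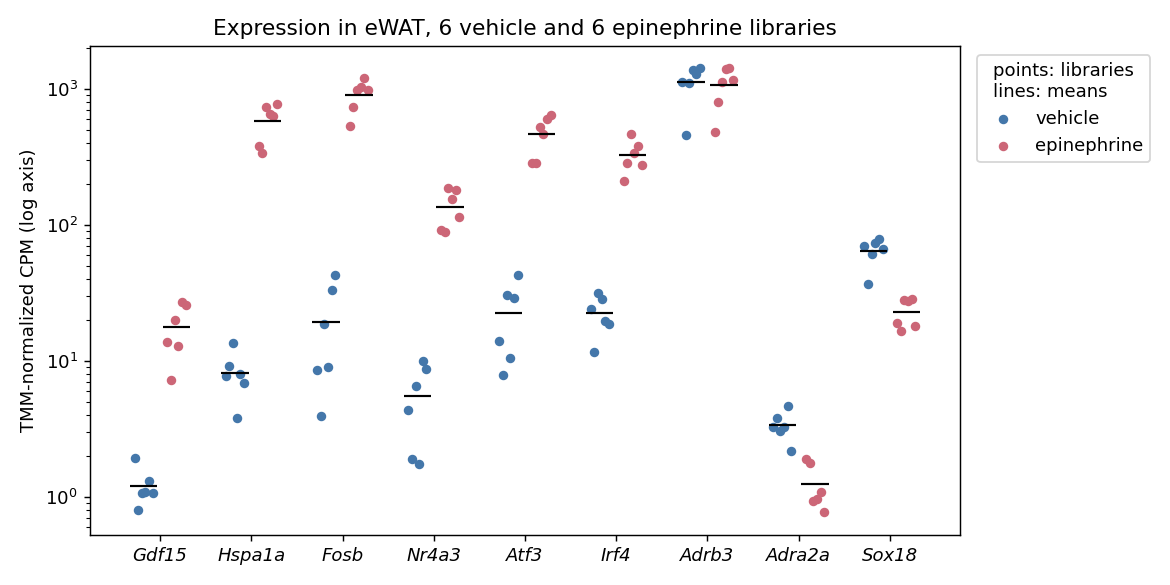
Expression of 9 genes in eWAT as TMM-normalized CPM on a log axis. Each point is a library, blue for vehicle and red for epinephrine (6 each), and lines are group means. Gdf15 lay above every vehicle library in all 6 epinephrine libraries, while Adrb3 overlapped between the groups.

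The adrenergic receptor gene Adra2a passed the test, while Adrb1 and Adrb3 did not. Adrb3 was at 1124 ± 351 CPM with vehicle and 1059 ± 362 CPM with epinephrine (SD, n = 6 each; log2 fold change -0.09, SE 0.30, edgeR adjusted p = 0.95). Adrb1 was at 7.10 ± 4.45 and 8.76 ± 3.70 CPM (SD, n = 6 each; log2 fold change 0.30, SE 0.41, edgeR adjusted p = 0.838). Adra2a, an alpha-adrenergic receptor that lowers cyclic AMP, fell to 0.370 of its vehicle level, from 3.35 ± 0.826 to 1.23 ± 0.479 CPM (SD, n = 6 each; log2 fold change -1.44, SE 0.27, edgeR adjusted p = 0.00788).

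In 58 of 100 splits of the 12 libraries, the real one included, camera with a preset correlation called 13 or more of the 31 gene lists, as it did for the real groups. The results of the lists therefore rest on their counts of genes and on the p with an estimated correlation, which passed for 6 lists. It passed for at most 2 in the other splits, a comparison added after the preset count was known. Those splits mix mice of both groups, so a low count there was likely beforehand and lends the 6 lists no support.

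Immediate early genes, which are transcribed within minutes of a stimulus, rose together. Of 26 measured, 18 were higher and 0 lower over all genes tested, and 21 higher when adjusted over the list alone (camera adjusted p = 4.03e-36; adjusted p = 0.0284 with an estimated correlation). The AP-1 genes Fosb and Jun rose 46.7-fold and 13.5-fold, to 907 ± 235 and 1579 ± 501 CPM (SD, n = 6 each). Fos was also higher, at 84.4 ± 55.4 CPM with vehicle and 809 ± 285 CPM with epinephrine (SD, n = 6 each; edgeR adjusted p = 0.00411). Genes known as targets of cyclic AMP signalling and its transcription factor CREB showed 12 higher and 0 lower of 20, and 12 when adjusted over the list alone (camera adjusted p = 4.12e-23; adjusted p = 0.0284 with an estimated correlation). The orphan nuclear receptors Nr4a3, Nr4a1 and Nr4a2 were among them, with log2 fold changes of 4.61 (SE 0.49), 4.25 (SE 0.46) and 3.56 (SE 0.18). Crem, a CREB-family repressor and activator gene, rose 3.74-fold. Other genes among the 12 largest rises were Atf3 (log2 fold change 4.38, SE 0.47), Apold1 (4.32, SE 0.40), Nts, which encodes the precursor of neurotensin (4.03, SE 0.44), Irf4, a transcription factor gene (3.86, SE 0.27), and Ccn1, which encodes a secreted matrix-associated protein (3.60, SE 0.39).

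Heat shock genes rose as well. Of 14 members, 13 were higher and 0 lower, and all 14 were higher when adjusted over the list alone (camera adjusted p = 2.03e-39; adjusted p = 0.0131 with an estimated correlation). The chaperone genes Hspa1a and Hspa1b went from 8.17 ± 3.19 to 583 ± 184 and from 16.9 ± 4.41 to 757 ± 210 CPM (SD, n = 6 each). They are near-identical copies, so the division of reads between them is uncertain. Dnajb1 and Hsph1, which assist and belong to the Hsp70 system, rose 11.9-fold and 12.2-fold.

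Genes of the integrated stress response, in which Atf4 drives adaptation to stress, showed 8 higher and 0 lower of 19, and 8 higher and 1 lower when adjusted over the list alone (camera adjusted p = 2.02e-08; adjusted p = 0.0284 with an estimated correlation). Gdf15 and Atf3 are members, and Atf4 itself rose 2.04-fold (log2 fold change 1.03, SE 0.09, edgeR adjusted p = 0.000108). Ppp1r15a, which restores translation, rose 4.18-fold. Amino acid synthesis genes of the list did not pass; Asns had a log2 fold change of -0.04 and Psat1 of 0.14. Trib3, at -0.57, was the lower gene of the list-alone count. MAPK feedback genes showed 6 higher and 0 lower of 14, and 7 when adjusted over the list alone (camera adjusted p = 3.11e-07; adjusted p = 0.0284 with an estimated correlation). Errfi1, an EGF receptor inhibitor, rose 6.29-fold and the phosphatase gene Dusp8 3.87-fold.

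Glucocorticoid targets showed 7 higher and 0 lower of 20, and 8 when adjusted over the list alone (camera adjusted p = 8.70e-12; adjusted p = 0.063 with an estimated correlation). The 7 were Cdkn1a, Dusp1, Errfi1, Gadd45g, Pdk4, Per1 and Sgk1, of which several belong to other lists, while Fkbp5 and Tsc22d3, at log2 fold changes of 0.24 and 0.40, did not pass. The p53 target list held 6 higher and 1 lower of 15, and 7 higher and 2 lower when adjusted over the list alone (camera adjusted p = 0.000203; adjusted p = 0.104 with an estimated correlation). Cdkn1a, a cell cycle inhibitor gene, rose 3.97-fold and Btg2 7.49-fold, and Sesn1 was the lower gene at -0.41 (edgeR adjusted p = 0.0187); its call ended with the replicate block (0.0548).

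Lipid handling genes changed in part. Of 17 fatty acid and PPAR targets, 4 were higher and 0 lower, and 6 when adjusted over the list alone (camera adjusted p = 4.04e-07; adjusted p = 0.063 with an estimated correlation). Pdk4, which limits glucose oxidation, rose 4.37-fold and Hilpda, which inhibits adipose triglyceride lipase, 4.20-fold. The lipid droplet coat gene Plin2 rose from 206 ± 60.1 to 598 ± 172 CPM (SD, n = 6 each; log2 fold change 1.53, SE 0.27, edgeR adjusted p = 0.00578), and Acot2 was the fourth. The list of lipolysis genes had a camera adjusted p of 0.0323, and an adjusted p = 0.919 with an estimated correlation. Pnpla2 and Lipe, the triglyceride and hormone-sensitive lipase genes, had log2 fold changes of 0.17 and 0.10. None of 18 lipogenesis genes passed (0 over all genes and 0 over the list alone; camera adjusted p = 0.0124; adjusted p = 0.62 with an estimated correlation), Dgat1 being nearest at log2 fold change 1.03 (SE 0.29, edgeR adjusted p = 0.0667; 0.0494 with the replicate block). Of 11 adipokine genes, 0 passed in either count (camera adjusted p = 0.221), and of 10 thermogenic genes 0 passed over all genes and 1 higher, Dio2, over the list alone (camera adjusted p = 0.103; edgeR adjusted p of Dio2 0.0593, and 0.0357 with the replicate block).

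Of 15 genes of insulin signalling and glucose uptake, 2 were higher, Irs2 (3.93-fold) and Trib1 (3.81-fold), and 3 when adjusted over the list alone (camera adjusted p = 0.00346; adjusted p = 0.485 with an estimated correlation). Of 20 cholesterol synthesis genes, Hmgcs1 (1.76-fold) and Insig1 (1.60-fold) were the 2 higher, in both counts (camera adjusted p = 0.00196; adjusted p = 0.485 with an estimated correlation). The mean log2 CPM of this list was highest in vehicle 2, epinephrine 1 and epinephrine 2 (5.44, 5.29 and 5.42), where the epididymal score was also highest. With that score as a covariate, 2 genes were higher and the median log2 fold change was 0.103 against 0.281 (camera adjusted p = 0.0415). Without those 3 libraries it was 0.179 (camera adjusted p = 0.00342). Hypoxia and glycolysis genes showed 3 higher of 17, Vegfa (2.42-fold), Slc2a1 (1.49-fold) and Pgk1 (1.19-fold), and 4 when adjusted over the list alone (camera adjusted p = 2.27e-05; adjusted p = 0.0131 with an estimated correlation). Of 18 circadian genes, the 2 higher were Nfil3, at 5.76-fold, and Per1, at 2.31-fold, and 3 were higher and 1 lower when adjusted over the list alone (camera adjusted p = 0.109); the lower one, Dbp, had an edgeR adjusted p of 0.114, and 0.0235 with the replicate block. Of 18 respiratory chain genes, 1 was higher in both counts, Cycs (1.32-fold; edgeR adjusted p = 0.0286, and 0.0911 with the replicate block; camera adjusted p = 0.165), and of 13 mitochondrial genome genes 0 passed in either (camera adjusted p = 0.712).

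Among the falls that the naming rule allowed, which needs non-overlapping groups, the largest were in genes of varied function. The chemokine gene Ccl12 fell from 6.03 ± 5.93 to 0.615 ± 0.167 CPM (SD, n = 6 each; log2 fold change -3.28, SE 0.69, edgeR adjusted p = 0.0143). It was at 5.36, 10.7 and 15.5 CPM in vehicle 3, 5 and 6, where Ccl2 was also highest in the group (85.6, 103 and 149 CPM), and at 1.08 to 2.35 CPM in the other vehicle libraries. Its call ended in limma-voom with sample weights (adjusted p = 0.135), in limma on the deposited VST values (0.0985) and within numbers 4 to 6 (edgeR, 0.0695) and numbers 1 to 3 (edgeR, 0.471). Sox18, a transcription factor gene of vascular and lymphatic endothelium, fell to 0.357 of its vehicle level, from 64.1 ± 14.8 to 22.9 ± 5.60 CPM (SD, n = 6 each; log2 fold change -1.49, SE 0.20, edgeR adjusted p = 0.0013). Aplnr, the apelin receptor gene, fell from 30.8 ± 6.61 to 11.8 ± 3.11 CPM (SD, n = 6 each; log2 fold change -1.38, SE 0.21, edgeR adjusted p = 0.00265). Other falls with non-overlapping groups were those of Snai1, Tnfsf10, Zfp128, Pcsk4, Mmp11, Kcna2, Tfap4 and Zkscan4, with log2 fold changes between -1.29 and -1.13.

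Few markers of the cell types of fat passed the test. Of 12 adipocyte markers 0 passed over all genes or over the list alone (camera adjusted p = 0.773, upward direction; median log2 fold change -0.01), and Fabp4 was at 6968 ± 2255 CPM with vehicle and 7923 ± 2106 CPM with epinephrine (SD, n = 6 each). No member passed in either count among 16 macrophage and monocyte markers (camera adjusted p = 0.497), 6 neutrophil (0.506), 9 B cell (0.165), 12 mesothelial (0.497), 8 skeletal muscle (0.712) and 19 epididymis and testis markers (0.103); the median of the skeletal muscle list was -0.12 and its mean 0.10. Single members moved elsewhere, in both counts: of 17 T cell and NK cell markers, Gzmb was higher and Ncr1 lower (camera adjusted p = 0.673), of 12 endothelial markers Cldn5 was higher (0.607), of 14 fibroblast and adipose progenitor markers F3 was higher (0.712), of 12 smooth muscle and pericyte markers Tagln was higher (0.0628) and of 8 red cell markers Hbb-bs was lower (0.364). With the replicate block the edgeR adjusted p of Ncr1 was 0.0782 and that of Hbb-bs 0.0598, so both calls ended, while Cd14 and Mylk passed at 0.0218 and 0.0416 and the epididymis and testis list at a camera adjusted p of 0.00629. Of 24 inflammatory cytokine and NF-kB target genes 0 passed in either count; their median log2 fold change was -0.25 and mean -0.20 while camera gave an upward direction (camera adjusted p = 0.506). With the replicate block Ccl4 passed, with edgeR adjusted p = 0.0288. Ccl2 differed widely within both groups, from 7.23 to 149 CPM among vehicle libraries and up to 69.2 CPM among epinephrine libraries.

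**Figure D2:**
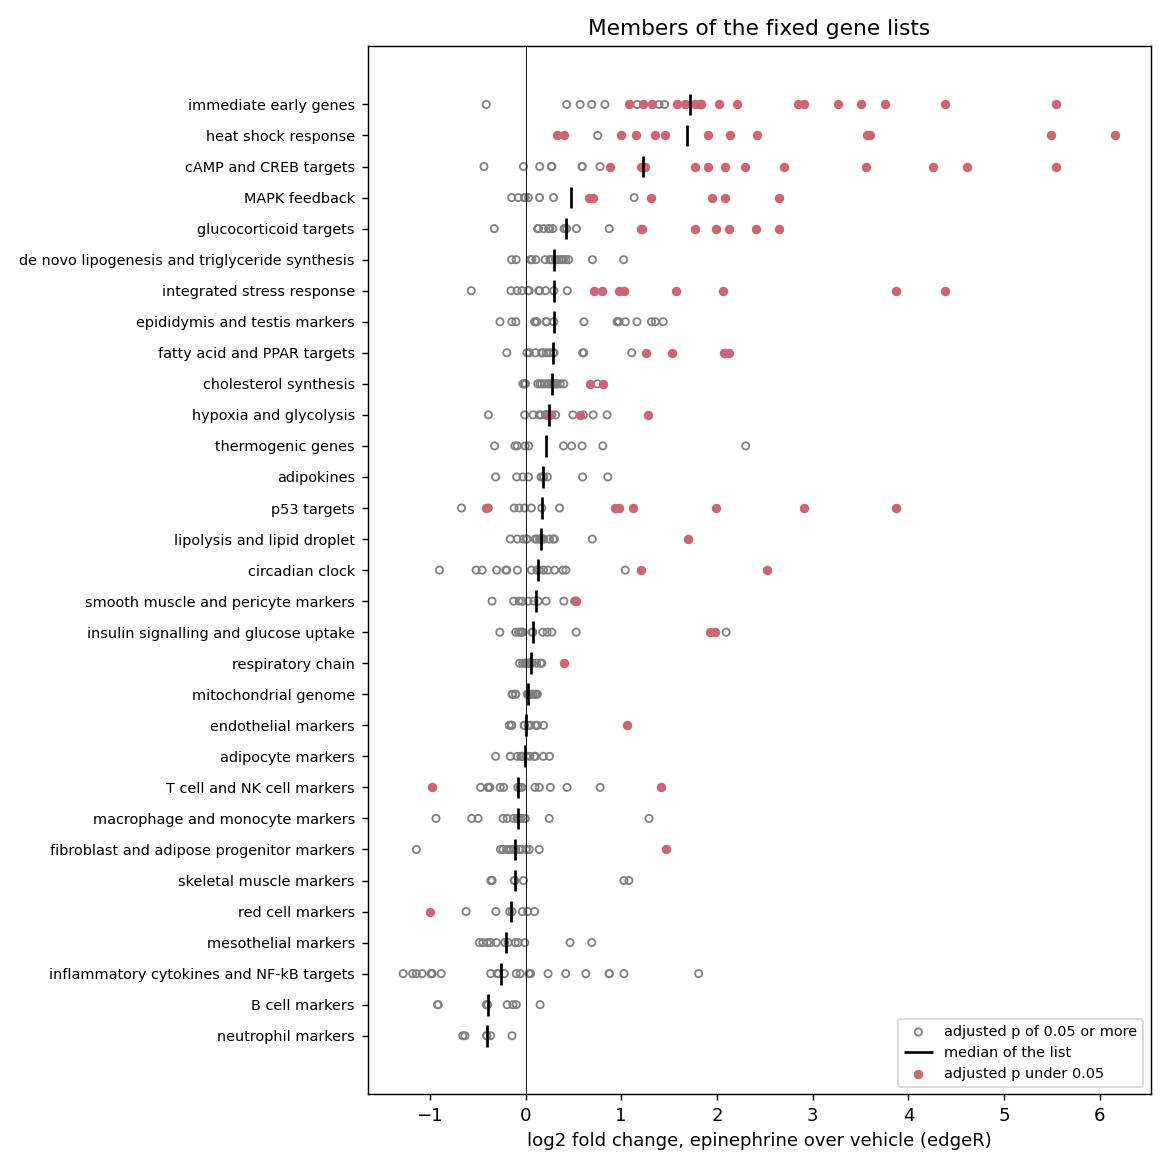
Log2 fold change of epinephrine over vehicle (edgeR) for the tested members of each of 31 gene lists. Red points have adjusted p under 0.05, open points do not, and vertical bars are list medians. Immediate early, heat shock and cAMP target lists had medians of 1.72, 1.68 and 1.23.

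Epididymal transcripts differed widely between libraries of both groups. The epididymis and testis list took between 0.00105% and 4.97% of counts among vehicle and between 0.00411% and 3.43% among epinephrine libraries. Its mean log2 CPM was 3.35 ± 3.82 with vehicle and 4.49 ± 3.34 with epinephrine (SD, n = 6 each; exact two-sided permutation test, p = 0.591, adjusted p = 0.739). This score followed the first principal component, which held 63.2% of the variance, with r = 0.964 (permutation test, p = 1e-05, the smallest it can give; adjusted p = 3e-05) and rho = 0.965 (permutation p = 2e-05, adjusted p = 6e-05). Without the 2 libraries farthest from the median, r was 0.957. The relation also held within each group, with r = 0.957 for vehicle and r = 0.973 for epinephrine (exact permutation p = 0.0042 in each) and rho = 0.943 in each (exact permutation p = 0.017). The 19 genes of the score are among those that the component was computed from. These p-values therefore do not compare independent measures. Adipocyte genes of the vehicle group were lowest in vehicle 2, the library with the highest epididymal share, where Fabp4 was at 2831 CPM against 6419 to 8762 CPM in the other vehicle libraries.

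**Figure D3:**
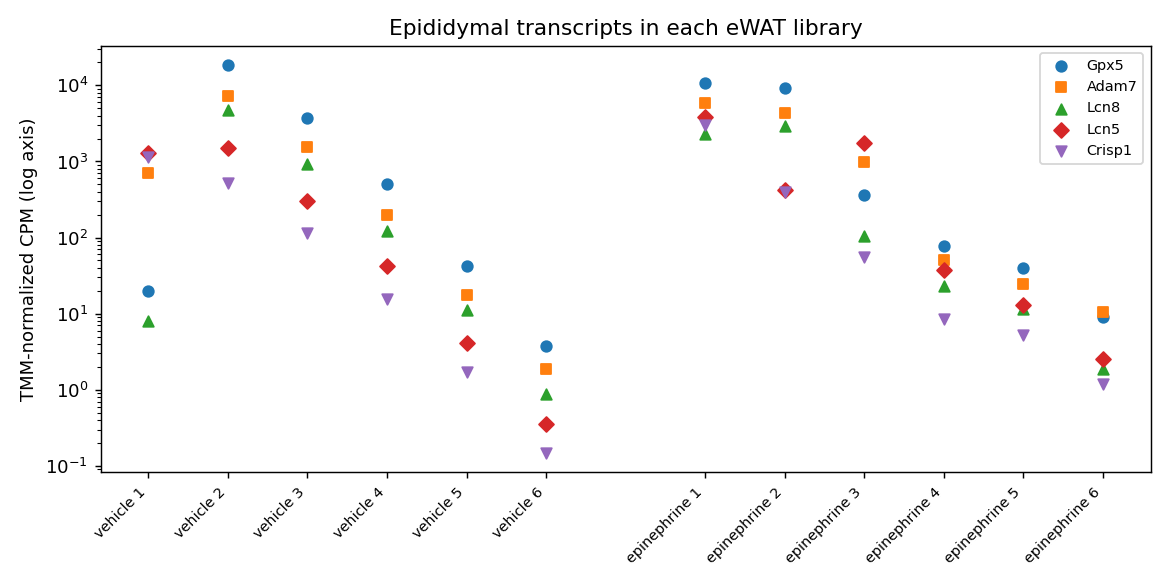
TMM-normalized CPM of 5 epididymal genes in each of the 12 libraries, on a log axis; each symbol is a gene. Gpx5 ranged from 3.81 CPM in vehicle 6 to 18353 CPM in vehicle 2.

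Without the 3 libraries in which Gpx5 exceeded 0.5% of counts, 786 genes were higher and 1028 lower, and with the epididymal score as a covariate 767 and 1002; both were chosen after seeing the data. With the replicate number as a block, edgeR called 385 genes higher and 365 lower, and within numbers 1 to 3 it called 0 in either direction (1356 at unadjusted p under 0.05; Gdf15 log2 fold change 3.43, adjusted p = 0.226), while numbers 4 to 6 gave 696 higher and 632 lower. Leaving out 1 library ended the call of Cldn5 unless it was vehicle 2 or 4 or epinephrine 1 or 2 (edgeR adjusted p up to 0.0847), of Insig1 unless it was vehicle 2 or 5 or epinephrine 1 or 6 (up to 0.0987), of Dusp1 unless it was vehicle 2 or 6 or epinephrine 1 or 2 (up to 0.0885) and of Cycs without vehicle 1 or 3 or epinephrine 2, 3, 4 or 5 (up to 0.0738). It ended the call of Ncr1 unless it was vehicle 2 or epinephrine 6 (up to 0.111) and of Hbb-bs unless it was vehicle 1 or 2 (up to 0.108), and both calls also ended with RLE scaling (0.0504 each). The listed ages, 12 to 17 weeks with vehicle and 18 to 23 weeks with epinephrine, do not overlap, so treatment and listed age cannot be told apart as a difference between the groups. They rise by 1 week from each library to the next across both groups, and whether they are the true ages of the animals is not settled here. With listed age as a linear covariate edgeR called 2339 genes higher and 1528 lower, of which 322 were among the 1007 genes called without it. Gdf15 passed (log2 fold change 3.21, edgeR adjusted p = 0.0098), while calls of named genes ended, among them those of Fos, Dusp1, Sgk1, Adra2a, Hilpda, Acot2, Plin2, Dusp10, Vegfa, Slc2a1, Pgk1, Trib1, Hmgcs1, Insig1, Btg2, Sesn2, Cycs, Gzmb, Cldn5, F3 and Tagln.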

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

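The comparison of epididymal profiles was chosen after the data were seen. In each group of 6 libraries, the highest or lowest value was set apart when its gap to the next, as a share of the whole range, exceeded the critical value of Dixon's test. This held for 37 of 342 groups of values, and chance gives about 1 in 20.

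Most of the values set apart were the lowest of the vehicle group and belonged to vehicle 2, the vehicle library with the most epididymal RNA. In TMM-normalized CPM these were Adrb3 at 459, Apold1 at 4.41, Sox18 at 36.5, Zkscan4 at 3.87, Angptl4 at 186, Plin2 at 90.7, Cdkn1a at 22.9, P4ha1 at 33.3, Irs1 at 37.1, Fabp4 at 2830, Aqp7 at 53.5, Mmp9 at 26.9, Cldn5 at 57.3, Tie1 at 66.9 and Actn3 at 5.28. In mean log2 CPM of a list, vehicle 2 was lowest for lipolysis (7.59), adipokines (6.89), fatty acid and PPAR targets (5.53), p53 targets (4.32), adipocyte markers (9.25), macrophage markers (4.97), endothelial markers (5.95) and fibroblast markers (7.01), and highest for cholesterol synthesis (5.44). Epinephrine 1, the epinephrine library with the most epididymal RNA, was lowest for Aplnr (6.03 CPM), Tnfsf10 (4.17), Thrsp (378) and Hmgcs1 (190).

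Elsewhere, Dnajb1 was lowest in vehicle 4 (38.1 CPM) and Cox7a2 lowest in epinephrine 6 (18.4). Epinephrine 3 was highest for Cxcr2 (3.28 CPM), Icam1 (121) and the neutrophil list (mean log2 CPM 3.76). Ncr1 was highest in epinephrine 6 (1.05 CPM), and Cr2 (0.879) and Fcer2a (2.02) were highest in vehicle 5. Epinephrine 2 had the highest total count of its group, 31700000.

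Vehicle libraries 2 to 5 carried epididymal transcripts in nearly constant proportions. Over 13 epididymal genes, vehicle 3, 4 and 5 held 20.3%, 2.74% and 0.241% of the level in vehicle 2. The SD of the log2 ratio was 0.0670, 0.0595 and 0.196 in these 3. It was 4.26 in vehicle 1 and 0.444, 0.751, 0.910, 1.18 and 2.13 in epinephrine 2, 5, 4, 1 and 3. The level fell in the order of the numbers, and vehicle 6 held 0.0223%, where 5 of these genes had at least 30 reads. Prm2, of the epididymis and testis list, was at 33.7, 6.55, 0.869, 0.130 and 0 CPM in vehicle 2 to 6. The titles do not say what the numbers order. RNA from one shared source in vehicle 2 to 5 is a candidate explanation that the small SDs in vehicle 3 to 5 prompted and so do not test. Separate pieces from one segment of the epididymis could give similar proportions, but how closely pieces from different mice would match was not measured. The SD of 4.26 in vehicle 1 shows only that its profile differs, so both explanations are still open. No biological explanation was tested, since the design names no group within vehicle.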

How the results depend on the processing

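The alternatives added after the data were seen are the epididymal covariate, the fit without the 3 libraries with most epididymal RNA and the fits within numbers. Gdf15 stayed past the threshold in every alternative fit except numbers 1 to 3 (3 libraries per group), where its log2 fold change was 3.43 and its edgeR adjusted p 0.226; the cause was not tested, and numbers 4 to 6, with as many libraries, gave 4.24 (edgeR adjusted p = 0.00151). Its log2 fold change was 1.67 on the compressed VST scale and up to 4.24 elsewhere.

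Against 428 genes higher and 579 lower, the epididymal covariate gave 767 and 1002, the fit without those 3 libraries 786 and 1028, 1 surrogate variable 978 and 1407, DESeq2 761 and 873, limma-voom with weights 1026 and 1503, and a threshold of 0.01 gave 228 and 185. Numbers 4 to 6 gave 696 higher, and numbers 1 to 3 gave 0 and 0 (1356 at unadjusted p under 0.05 in edgeR). Library-size scaling gave 1448 lower, and the replicate block 365 lower. The epididymal covariate and surrogate variable fits shared all 1007 genes, while the replicate block shared 651 of them (64.6%). Changed at least 2-fold were 337 higher and 159 lower in limma-voom, 110 higher and 3 lower on VST values, 316 higher in numbers 4 to 6, 0 and 0 in numbers 1 to 3, 129 lower in DESeq2, 149 lower with library-size scaling and 133 lower without the 3 libraries. Leaving out single libraries gave 276 (without vehicle 4) to 797 (without epinephrine 1) lower genes, and 54 to 113 past 2-fold. The cause of these shifts was not tested.

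Listed age as a covariate gave 2339 higher and 1528 lower genes, 1880 and 708 of them past 2-fold, and shared 322 of the 1007. Ages do not overlap between groups, so the fit extrapolates a line. Within both groups the epididymal score was lower at numbers 4 to 6, where listed age is higher, so the line also follows epididymal RNA. Under it the log2 fold changes of Spry4, Per1, Dusp1, Tsc22d3 and Gpx5 changed sign, to -0.0907, -0.0427, -0.546, -0.949 and 13.2, and these lists reversed: lipolysis (camera adjusted p = 0.0022), adipokines (0.0152), lipogenesis (0.215), cytokines (0.000295), insulin signalling (0.14), respiratory chain (0.0431), adipocyte (0.000295) and endothelial markers (0.00314). In numbers 1 to 3 the red cell list reversed (0.0196) and 20 lists passed. Of 13 lists past the preset camera threshold, 6 passed with an estimated correlation. With fry's directional test the lipolysis, lipogenesis, insulin and cholesterol lists did not pass (adjusted p = 0.62, 0.328, 0.0988 and 0.247). The preset camera call of the lipolysis list also ended without vehicle 1 or 2 or epinephrine 3, 4, 5 or 6, that of lipogenesis without vehicle 1 or 2 or epinephrine 4, and that of insulin signalling without vehicle 2.

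With the replicate block, the calls of Dgat1, Dio2, Ccl4, Dbp, Cd14 and Mylk were gained, those of Cycs, Ncr1, Hbb-bs, Sesn1, Gbp4 and Igtp lost, and the epididymis and testis list passed; it changed no other call of a named gene or list. Over the named genes other than Gdf15 and all alternatives, 3926 results kept their side of the threshold (78 of these changed sign with neither value past it), 189 fell below it, 136 passed it and 5 reversed. In the simulation 52.0% of 2-fold changes were recovered, so changes of that size can be missed at this number of libraries.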

Other observations

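The 3 lists and the single genes of the first 2 paragraphs, the covariate and age tests and the count of lists with an estimated correlation in other splits were chosen after the data were seen. The last was added once the preset count was known to be matched by other splits. Genes of vascular transcription factors and receptors were lower for 4 of 16, Sox18, Aplnr, Tmem88b and Gata2, with 0 higher. Tmem88b had a log2 fold change of -1.53 (SE 0.30, edgeR adjusted p = 0.0103) and Gata2 of -0.62 (SE 0.09, edgeR adjusted p = 0.00233). As a set they did not pass (downward with camera, median log2 fold change 0.01, camera p = 0.184; p = 0.662 with an estimated correlation). Of 20 interferon response genes 3 were lower, Trim21 (-1.09, SE 0.11), Gbp4 (-1.49, SE 0.35) and Igtp (-0.70, SE 0.18), and 0 higher (camera p = 1.37e-06; p = 0.194 with an estimated correlation). With the replicate block the calls of Gbp4 (edgeR adjusted p = 0.0514) and Igtp (0.124) ended.

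Liver transcripts were highest in epinephrine 4, where Alb, encoding serum albumin, was at 206 CPM against 2.96 to 27.7 CPM in the other libraries, and Apoa1 at 29.7 CPM against 0.181 to 5.63. Of 13 liver genes 0 passed in edgeR (camera p = 4.01e-05; p = 0.214 with an estimated correlation), and 8 were higher with the epididymal score as a covariate. The neutrophil chemoattractant gene Cxcl1 was at 102, 68.9 and 119 CPM in vehicle 3, 5 and 6 and at 106 CPM in epinephrine 3, against 1.59 to 18.4 CPM in the other 8. Il6 was at 5.79, 11.4, 18.1 and 10.8 CPM in the same libraries and at most 2.31 elsewhere. Ccl12 was also highest in vehicle 3, 5 and 6, but at most 0.758 CPM in every epinephrine library.

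The real groups gave 1007 genes, the most in 100 splits of the 12 libraries, where 1 split, the real one, gave as many and the highest of the others was 1. The 282 genes past 2-fold were likewise matched by 1 split of 100, the real one, with 1 as the highest other. Among the 32 splits that part every same-numbered pair, 1 gave 1007 and the others at most 1. For gene counts, a random division of the libraries thus rarely gave as many genes, at this number of splits. Every other split mixes mice of both groups, which widens the spread within its sides, so a low count there was likely beforehand. None of the 100 splits put all libraries numbered 1 to 3 on one side. For lists a random division did give as many: 58 of 100 splits gave at least the 13 lists called with the preset correlation, and up to 25, and the cause was not tested. With an estimated correlation, 1 of 100 gave the 6 lists of the real groups and the others at most 2. That low count too was likely beforehand, since the other splits mix mice of both groups.

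The genes higher with epinephrine were weighed against unequal epididymal tissue and a steady trend with listed age. With the epididymal score as a covariate, their median log2 fold change was 0.973 against 0.954, a ratio of 1.02, and all 428 were still higher. This argues against the amount of epididymal RNA, as this 1 mean score measures it, as the cause. The score does not capture the differing epididymal profiles of the libraries, and its group means differed little against their spread. Within groups, their median slope of 0.06 per week times the 6 weeks between group means came to 0.377 of that median (0.284 to 0.462 leaving out 1 library), 0.209 with the slope of vehicle alone (0.0332 per week) and 0.556 with that of epinephrine (0.0884). Within each group listed age rises with the number, along which the epididymal score fell. It went from 8.47 in vehicle 2 to -2.10 in vehicle 6, with vehicle 1 at 4.04, and from 8.46 in epinephrine 1 to 0.564 in epinephrine 6. The slopes therefore mix listed age with epididymal RNA. A trend with listed age is thus not excluded and cannot be told apart from epinephrine itself, since the ages do not overlap, and whether they are the true ages is unsettled. Time and place of collection were not tested.

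Of the 579 genes lower with epinephrine, 554 had a gene type. They held more genes of any type other than protein-coding, 59 of 554 (10.6%), than genes that were not called, 967 of 14815 (6.53%; Fisher's exact test, p = 0.000348). These other types were not told apart. Genes higher with epinephrine held 24 of 415 (5.78%, Fisher's exact test against genes not called, p = 0.614). Low expression of such genes could give the excess among lower genes. At an average log2 CPM of at least 3, however, the shares of lower and not called genes were 3.67% (13 of 354) and 1.35% (137 of 10149) (Fisher's exact test, p = 0.00165). This argues against expression below that level as the whole cause. Expression above that level was not matched between lower and not called genes, and the test treats genes as independent. Overlap with other genes on the opposite strand was not tested, and no biological explanation was tested.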
